A study of Vigna radiata with 18 samples.

How the data were processed

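Chromatin accessibility was measured by ATAC-seq, in which the transposase Tn5 cuts and tags open DNA in nuclei, in leaves of mung bean (Vigna radiata) of the cultivar Weilv 9. Per the labels, 18 libraries fall into 6 groups of 3 replicates. The treatment T1 was a first bath in 100 mM NaCl for 24 h, a recovery of 48 h without NaCl and a second bath in 100 mM NaCl. The treatment T2 was 100 mM NaCl without the earlier exposure. Leaves were taken at 0, 6 and 48 h of the last bath. Per the labels' protocols, about 50000 nuclei from frozen leaf entered each library, Tn5 acted for 30 min at 37 °C, the libraries had 11 to 13 PCR cycles, and reads were paired, 150 bp each. The labels also carry the cell type tag protoplast, which the protocol does not describe.

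A single list of consensus peaks was used. The deposited list has 3 columns, chromosome, start and end, with no header, no score and no column of a sample, so 0 of its columns belong to a library. It holds intervals and not counts, and no library total, coverage or peak height stands in it. The depth behind each peak is therefore unknown, and no interval or detection limit that needs depth was computed. Per the submitters' processing notes, the tools named were fastp 1.0.1, Bowtie2, deepTools 3.5.6, SAMtools 1.22.1, MACS3 3.0.3, bedtools 2.28.0, featureCounts 2.1.1, edgeR 4.0 as used by the authors, and R 4.4.3. Their roles, the peak threshold, the treatment of duplicate, multiply mapped and organelle reads, the shift of reads for the Tn5 cut, the libraries that were merged and the genome build are not given in the sources used here. Each of these choices bears on the list: a stricter threshold shortens it, discarding multiply mapped reads empties repeats, and joining peaks from several libraries widens them.

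The comparison of T1 with T2 at each time, of 6 and 48 h with 0 h, and of the replicates needs a value per library and was not made. A gene table of the VC1973A assembly was at hand. It is of another build: on 11 of 11 chromosomes peaks lay past the last gene of that table, 17572 peaks in all. Coordinates were not joined to it, and no genome sequence was used. The planned shares of promoter peaks, gene lists, named genes and motifs were therefore not computed, and the planned relation of peak density to gene density was replaced by peak density alone. No gene is named for this reason.

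From the intervals were computed, with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, the widths, the gaps between neighbours, and peak numbers in bins of 1 Mb. The span of a chromosome was taken from its first base to the end of its last peak, since chromosome lengths are not given in the sources used here. Density in the outer 40% of the span (20% at each end) was set against that in the central 20%, per chromosome, with bins placed by their centre, and compared with an exact two-sided sign-flip permutation test of the log2 folds. Rank correlation (Spearman) of peak number and median width over bins with at least 5 peaks was computed within each chromosome and tested over chromosomes in the same way. The density of each chromosome was compared with that of the others by a two-sided permutation test that exchanged blocks of about 5 Mb (100000 draws), with Benjamini-Hochberg adjustment over 11 chromosomes, and its 95% interval came from 10000 bootstrap draws of its blocks. Gaps were compared with 1000 random placements of the same peaks inside the same 100 kb, and long spans with 1000 placements anywhere on the same chromosome. Windows of 100 kb, moved in steps of 10000 bp, were ranked by the bases of the peaks centred in them and compared with 200 placements inside the same 1 Mb. Chromosomes, blocks and bins are parts of one list and not biological replicates, so no p-value measures a spread between plants or libraries. The sign-flip and block tests measure the spread over chromosomes or blocks of this genome. The tests against random placements or reorderings of peaks measure only the departure from those random positions or orders.

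The calculations were tested on simulated data made with 50238 peaks. Uniform peaks gave a fold of 1.01 between outer and central parts, and a central part thinned by 50% gave 1.96. Of 2000 planted close pairs, 1977 were recovered as added short gaps. With equal density 0 chromosomes passed the adjusted threshold, and chromosome 5 thinned by 30% came out at 0.688 of the others. The positions in these lists were independent. They do not show how often the block test gives false calls where sparse bins lie in long runs. Alternatives were set before the data were examined for the peak set (merging of peaks closer than 150 bp, leaving out the narrowest 25%) and for the planned relation of peak density to gene density (bins of 500 kb and 2 Mb, bases in place of peaks), and the latter were applied to the contrast that replaced it. All other alternatives were added after the data were seen. The tests themselves were also chosen after the data were seen, since the planned ones could not be run: the contrast of outer and central parts was taken up after peak numbers along the chromosomes had been looked at, the range of short gaps was read from the distribution of gaps, and the limits of 100 and 200 kb for peak-free spans and the windows of 100 kb were set after looking at the list. Their p-values do not allow for that choice. Coordinates are 1-based, on the chromosomes as the list names them.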

Results

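ATAC-seq profiled open chromatin in mung bean leaves under 2 salt regimes, direct exposure to NaCl and exposure after an earlier salt bath and recovery, at 3 times. The 6 groups held 3 libraries each, 18 in all. The design asks how an earlier salt exposure and the time in salt change accessibility. The list analysed here is one set of consensus peaks for the series, with a position and no value for any library. No difference between the regimes or times can be drawn from it, and what follows describes where leaf chromatin was called open on the 11 chromosomes.

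The list held 50238 peaks that did not overlap, with a total of 18.04 Mb. This was 3.62% of the 498.8 Mb between the first base of each chromosome and its last peak. Peaks were short. The median width was 292 bp, with quartiles of 201 and 447 bp and a mean of 359 bp ± 233 (SD over peaks). The narrowest peak was 105 bp, 95% of peaks were 812 bp or shorter, and 30 peaks exceeded 2000 bp. Median width differed little between chromosomes, from 279 bp on chromosome 5 to 299.5 bp on chromosome 7. All peaks lay on the 11 chromosomes.

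Peaks were spread over every chromosome, with 101 per Mb on average. Chromosome 8 held 8450 peaks, 16.8% of the list, and chromosome 4 held 2973. Chromosomes 1 and 5 were sparser than the rest. Chromosome 5 had 76.8 peaks per Mb (95% block bootstrap interval 62.0 to 90.2), 25.5% below the 103 per Mb of the other chromosomes. Chromosome 1 had 78.9 per Mb (55.1 to 102.6), 23.2% below the 102.7 per Mb of the others. The remaining 9 chromosomes ranged from 99.3 per Mb on chromosome 3 to 112 per Mb on chromosome 8. In the block permutation test, chromosome 5 (adjusted p = 0.0228) and chromosome 1 (adjusted p = 0.0406) passed the threshold among 11 chromosomes. Chromosome 8 was 14.0% above the others and did not pass the block permutation test (permutation p = 0.0395, adjusted p = 0.145). With blocks of 10 Mb neither low call passed (adjusted p = 0.188 for both), nor did either when peak-free spans of 100 kb or more were taken out of the length (0.0975 for chromosome 5 and 0.235 for chromosome 1). Without the narrowest 25% of peaks the call for chromosome 1 ended (adjusted p = 0.0524) and that for chromosome 5 did not (0.0177). Blocks of 2 Mb gave the lowest values, 0.0028 for chromosome 1 and 0.00154 for chromosome 5. Sparse 1 Mb bins lay side by side on both chromosomes, so neighbouring blocks are not independent. Small blocks, also those of 5 Mb, can therefore make the p-value too low.

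**Figure D1:**
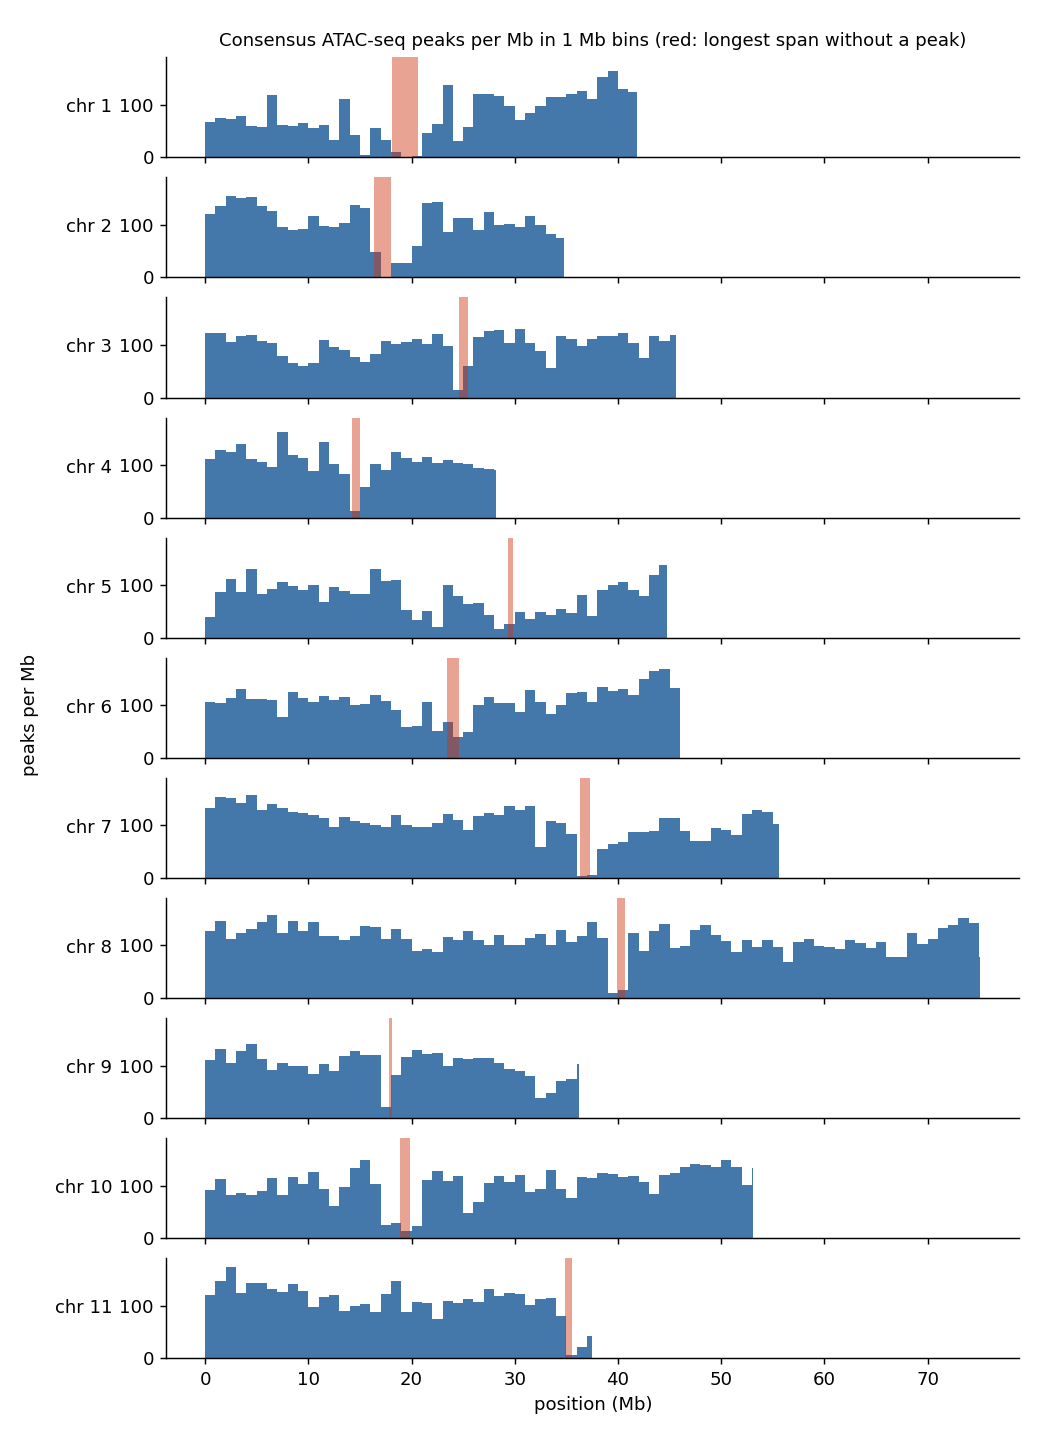
Consensus peaks per Mb (vertical axes) in 1 Mb bins along each of the 11 chromosomes (position in Mb from the first base), with the last bin ending at the last peak; the red band is the longest span of that chromosome without a peak. Density is lowest in an interior region on 10 chromosomes and near the far end on chromosome 11, and the longest red band is the 2.52 Mb span of chromosome 1.

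On average the ends of the chromosomes held more peaks per Mb than their centres. The outer 40% of the span had 110 peaks per Mb ± 10.3 (SD, n = 11 chromosomes) and the central 20% had 86.0 ± 23.3. The outer part was denser on 9 of 11 chromosomes, by 1.33-fold on average, a mean log2 fold of 0.41 ± 0.45 (SD). The fold was 2.52 on chromosome 1, 1.92 on chromosome 2 and 1.67 on chromosome 6. On chromosome 9 (0.926) and chromosome 11 (0.989) the centre held slightly more peaks per Mb than the ends. The exact two-sided sign-flip permutation test over 11 chromosomes gave p = 0.00586, which was also the adjusted value over the 3 tests of this family. The contrast of outer and central parts was chosen after the peak numbers along the chromosomes had been seen. The ends of one chromosome were not alike: the first 20% of chromosome 1 had 73.8 peaks per Mb and the last 20% had 128, whereas on chromosome 11 the first 20% had 141 and the last 20% had 77.6. Once peak-free spans of 100 kb or more were taken out of the length, the average fold was 1.03 and the call was lost (exact permutation p = 0.363).

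**Figure D2:**
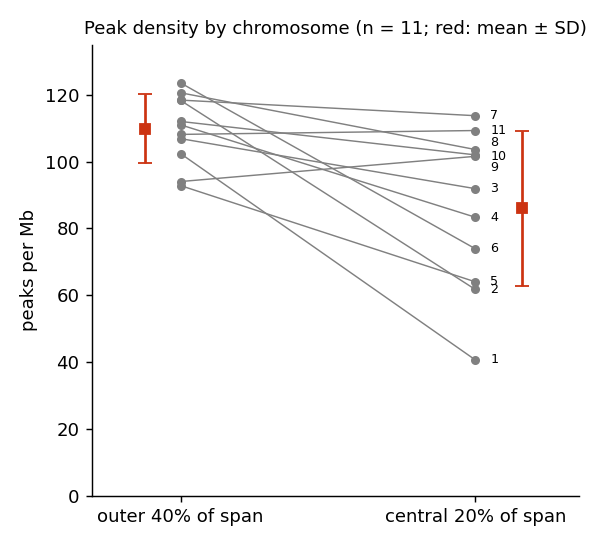
Peaks per Mb (vertical axis) in the outer 40% and the central 20% of the span of each chromosome; grey points joined by a line are 1 chromosome each, numbered at the right, and red squares with bars are the mean ± SD over 11 chromosomes. The mean falls from 110 to 86.0 peaks per Mb, and chromosome 1 falls the most, from 102 to 40.6.

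Each chromosome had at least 1 region nearly free of peaks. The sparsest 1 Mb held between 0 and 13 peaks on the 11 chromosomes, against medians of 74 to 114 per window. It held 0 peaks on chromosome 1, chromosome 2 and chromosome 6. The longest span without a peak ran for 2.52 Mb on chromosome 1 (18139876 to 20661530), for 1.66 Mb on chromosome 2 (16336400 to 17998530) and for 1.22 Mb on chromosome 6 (23390480 to 24606081). It was 972 kb on chromosome 7, 931 kb on chromosome 10, 836 kb on chromosome 3, 820 kb on chromosome 8, 739 kb on chromosome 4 and 684 kb on chromosome 11. The shortest of these longest spans were 481 kb on chromosome 5 and 260 kb on chromosome 9. On 10 of 11 chromosomes the longest span met the sparsest 1 Mb, the exception being chromosome 5, where the sparsest 1 Mb lay at 19300001 to 20300000 and the longest span at 29303833 to 29784955.

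In all, there were 62 spans of 200 kb or more between neighbouring peaks, with a total of 28.1 Mb. The limit was chosen like that of 100 kb after the spans were seen. Stretches before the first peak of a chromosome were not counted among the spans. The first peak started at 376119 on chromosome 5 and at 131352 on chromosome 1. Where spans of 100 kb or more were taken out of the length, such stretches were taken out too. The longest span between neighbours in 1000 random placements of the same peaks on the same chromosomes was 191 kb, below the limit of 200 kb. Spans of 100 kb or more numbered 177, against a mean of 3.08 and at most 10 in the placements (p = 0.001, one-sided permutation test, the smallest they can give). Chromosome 5 held 16 of the 62 spans, chromosome 10 held 9 and chromosome 1 held 8. The middle 60% of the chromosomes held 55 of them and the outer 40% held 7. Chromosome 11 was the exception in position: its longest span lay at 34837185 to 35521464, centred at 93.9% of the chromosome's span, and a second of 552 kb followed at 35819790 to 36371589.

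Peak width rose weakly with the number of peaks per bin. In bins of 1 Mb, median width and number of peaks were positively correlated on 10 of 11 chromosomes, with a mean Spearman rho of 0.21 ± 0.13 (SD, n = 11 chromosomes), from -0.085 on chromosome 9 to 0.343 on chromosome 6. The exact sign-flip permutation test gave p = 0.00195 (adjusted p = 0.00293). These are correlations across bins, which are not independent replicates. Peak numbers were not divided by bin length here, so the short last bins of chromosomes could count as sparse. Median width was 278 bp in bins with at most 86 peaks and 297 bp in bins with more than 120. Peaks in the outer 40% of the span had a median width of 302 bp and those in the central 20% one of 275 bp. The difference of the medians was 26.7 bp ± 9.58 (SD, n = 11 chromosomes). Outer peaks were wider on 11 of 11 chromosomes (exact permutation p = 0.000977, the smallest the test allows, adjusted p = 0.00293). This held also on chromosomes 9 and 11, where the outer part was not denser (folds of 0.926 and 0.989). Width thus went with position where density did not, and the effects of position and density were not separated. The correlation depended on the bin size, with a mean rho of 0.078 in bins of 500 kb and 0.33 in bins of 2 Mb.

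Short gaps between neighbouring peaks were more frequent than random placement inside the same 100 kb gives. The median gap was 5.77 kb, with quartiles of 2.16 and 11.6 kb. Gaps of at least 150 bp and under 700 bp, a range chosen from the observed gaps, numbered 4501, 8.96% of all, against a mean of 3164 (central 95% 3062 to 3263) when the same peaks were placed at random inside the same 100 kb. The ratio was 1.42 (p = 0.001, two-sided permutation test, the smallest 1000 placements can give). The excess was 1.62-fold for gaps of 200 to 300 bp and 1.03-fold for gaps of 1000 to 1500 bp. Gaps under 100 bp numbered 68, against 604 in the placements, which left any gap free, whereas peak calling and the merging of libraries can join intervals this close. When placed peaks were also kept at least 100 bp apart, the ratio for 150 to 700 bp was 1.38 (p = 0.001, two-sided permutation test).

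**Figure D3:**
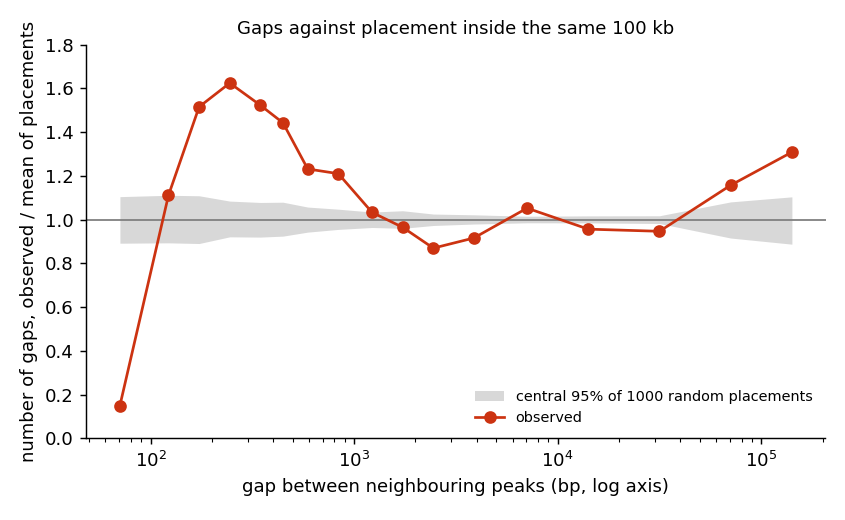
Number of gaps between neighbouring peaks divided by the mean of 1000 random placements inside the same 100 kb (vertical axis) against the gap in bp (log axis); red points are the observed list, and the grey band is the central 95% of the placements. The observed ratio is 0.15 for gaps of 50 to 100 bp, reaches 1.62 at 200 to 300 bp and returns to 1.03 at 1000 to 1500 bp. It is 0.87 at 2000 to 3000 bp and 1.31 at 100 to 200 kb.

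A single region of chromosome 11 stood apart in the other direction. At 18040001 to 18140000, 44 peaks covered 40.0 kb, 40.0% of the window, against 3.61% in the median window of 100 kb and at most 21002 bp in any of 200 placements that kept the density of each 1 Mb. This region held 3 of the 5 widest peaks of the list, at 18081949 to 18086691 (4743 bp), 18117503 to 18121885 (4383 bp) and 18128998 to 18132811 (3814 bp). The other 2 were on chromosome 6 at 30243418 to 30247128 (3711 bp) and on chromosome 5 at 34894489 to 34898050 (3562 bp). All 7 peaks over 2000 bp of chromosome 11 fell in a stretch of 86.5 kb of this window, while the other 10 chromosomes shared 23.

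A window of chromosome 4 at 7420001 to 7520000 held more peaks, 48 against at most 34 in any placement, with 23.0 kb covered, and was the only other one above the highest placed value. None of its peaks exceeded 2000 bp, and the widest was 1953 bp. On chromosome 7, 39980001 to 40080000 held 19 peaks over 17.6 kb with 3 peaks over 2000 bp, within the range of the placements. These windows were chosen for their values from the list that they describe.

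**Figure D4:**
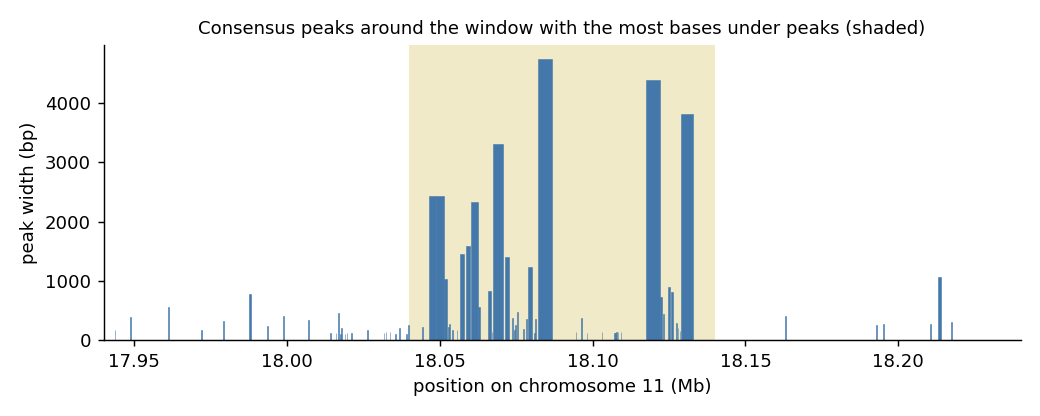
Width in bp (vertical axis) of each consensus peak from 100 kb before to 100 kb after the densest window of chromosome 11; each bar is 1 peak drawn to scale along the chromosome, and the shaded area is the window from 18040001 to 18140000. The 7 peaks over 2000 bp stand inside the shaded area, and the widest is 4743 bp.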

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

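The alternatives for the peak set were chosen before the data were seen, as were bin size and bases under peaks for the density along chromosomes, though for another test, and all others after. The excess of short gaps (1.38 to 1.49) and the relation of width to density (rho 0.078 to 0.33) kept their direction and their side of the threshold under the alternatives tried for them. Of 35 alternatives with a test, 29 left the call in place, 6 lost it and 0 reversed it. Many of the 29 were runs of the outer-to-central fold with chromosomes left out, which share most of their data, so the tally does not count independent checks. The relation of width to density passed narrowly in 500 kb bins (exact sign-flip p = 0.040) and without the narrowest 25% of peaks (exact sign-flip p = 0.042). A further 8 alternatives gave values with no test. Merging peaks closer than 150 bp left 49838 of 50238 peaks, and dropping the narrowest 25% left 37530, with 70 long spans in place of 62. The fold of outer over central density was 1.33 in 500 kb bins, 1.34 in 2 Mb bins and 1.38 for bases under peaks, and 1.24 to 1.37 when any 1 chromosome was left out, and 1.18 without chromosomes 1 and 2. With peak-free spans of 100 kb or more taken out, the fold was 1.03 and not past the threshold. The same change left chromosome 1 at 0.891 and chromosome 5 at 0.860 of the other chromosomes, both no longer past it. Blocks of 10 Mb left the ratios at 0.768 and 0.745 with fewer units to permute, and both calls were lost, whereas blocks of 2 Mb kept both (adjusted p = 0.0028 and 0.00154). Because sparse bins lay in runs, the blocks of 2 Mb are not independent units, and their lower values are no stronger support. Dropping the narrowest peaks left chromosome 1 at 0.759 with its call lost, and the cause was not tested. No paired analysis was possible because the list holds no column of a library, and for that reason no replicate could be left out. The alternatives planned for promoters, gene lists, motifs and differential accessibility were not run. Read depth is unknown, so whether a span without peaks reflects low coverage cannot be read from the list.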

Other observations

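The tests of repeats on chromosome 11 were chosen after the data were seen and revised after their results were seen, and the other tests below were set before their results were seen, except that the limit of 100 kb came from looking at the spans, that the interval condition for chromosomes 1 and 5 was added later, and that the simulation of joined peaks and the count of remaining gaps were added after the correlations and gaps were seen. Chromosome 11 had no sparse region in its interior. Between 20% and 80% of its span its sparsest 1 Mb, at 22000001 to 23000000, still held 75 peaks, whereas the same measure gave 0 to 13 peaks on the other 10 chromosomes. Its sparse region lay near the far end instead, where the sparsest 1 Mb (34900001 to 35900000) held 6 peaks. On chromosome 9 the last 20% of the span had 72.0 peaks per Mb against 117 in the first 20%.

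The lower density of chromosome centres may lie mostly in long spans without peaks. Taking spans of 100 kb or more out of the length moved the fold of outer over central density from 1.33 (SD of log2 folds 0.45) to 1.03 (SD 0.13), and 6 of 11 chromosomes were then denser outside. In simulated peaks the same step left an evenly thinned centre at 1.88 but brought a centre emptied in blocks to 0.917, so it can separate these simulated cases, with a lean towards the spans. A centre thinned in patches, or a fold near 1.33, was not simulated, so the step does not settle such a case. The spans are not shown to be the whole of the difference for chromosome 5, which moved from 0.745 to 0.860 of the others (permutation p = 0.00886, interval 88.0 to 104 per Mb against 112), although adjustment over 11 chromosomes ended its call (adjusted p = 0.0975). For chromosome 1, at 0.891 (permutation p = 0.0428, interval 85.7 to 115 against 111), the question is left open: the p alone met the condition set beforehand against the spans as the whole cause, but the bootstrap interval, required only after that p was seen, includes the density of the others. Whether the spans are closed chromatin, repeats in which reads cannot be placed, or unsequenced bases stays open, since no sequence was used, and no biological explanation was tested.

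Wider peaks in denser regions could come from close peaks that the calling joined. Among the 37560 peaks with no neighbour within 1000 bp, the mean rank correlation of width and density was 0.194 ± 0.157 (SD over chromosomes), against 0.21 for all peaks, and it was positive on 10 of 11 chromosomes (exact sign-flip permutation p = 0.00391). That met the condition set beforehand against joining. The condition cannot decide alone, because leaving out peaks with near neighbours changed the correlation little in simulated lists of joined peaks. This was seen in 20 simulated lists with widths unrelated to density and neighbours closer than 500 bp joined. All peaks gave 0.071 ± 0.035 there (SD over lists), and isolated peaks still gave 0.066 ± 0.041, above the bound of 0.05. No list without joining was simulated at the local density, so the part of these values made by joining is unknown. Both simulated values lie below the observed ones. Joining at one fixed distance in the final list would leave no gap below that distance. The list holds gaps down to 1 bp and 68 gaps under 100 bp, which argues against such joining. It also holds 3448 gaps of 100 to 500 bp, against a mean of 2338 in local random placements. None of the 5 classes of gaps in this range lies below the placements. Joining inside single libraries is not covered, since gaps can then stand between peaks of different libraries. In the simulated lists, joining below 100 bp gave 0.035 ± 0.044 over all peaks and joining below 300 bp gave 0.046 ± 0.054. The simulated lists took their widths and local density from the final list, thus from after any joining. They also lacked the excess of short gaps seen in the list. Their lower values therefore cannot decide how much of the relation joining made. Joining inside single libraries, and the merging of overlapping intervals from several libraries, which leaves no gap to count, stay open. So does a width that follows the local read depth, because the list gives no signal.

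The block of wide peaks on chromosome 11 may be a repeated or inserted sequence that collects reads from several copies. Direct repeats were tested by the highest autocorrelation of peak coverage at shifts of 5000 to 50000 bp, which was 0.271 against a median of 0.246 over 200 reorderings of the same peaks and gaps (permutation p = 0.289), which does not decide. For inverted repeats the highest mirror correlation of 30000 bp arms was 0.671 against a median of 0.422 (permutation p = 0.005, the smallest 200 reorderings can give), yet at most 5 peak edges coincided within 40 bp under one mirror point, against a median of 6. A high mirror correlation without matching edges leaves inverted repeats undecided. The reorderings also broke up any grouping of wide peaks, so a low p need not mean mirroring. Neither measure was tried on planted repeats. These are the last of 3 forms of the tests: the first, with shorter shifts and arms against random placement, passed for direct and inverted repeats and was discarded because near shifts and single wide peaks correlate by construction, and the second, with the present shifts and arms against random placement, passed for inverted repeats alone. An insertion of organelle DNA would need the sequence to test, and no biological explanation was tested.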
